A study of Mus musculus with 12 samples.

How the data were processed

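Total RNA of primary cortical neurons was measured in 12 libraries: 3 each of DMSO 16 h, erinacine S 16 h, DMSO 48 h and erinacine S 48 h. Libraries were made with a strand-specific kit and sequenced on an Illumina instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The tools named are bcl2fastq 2.20, Trimmomatic 0.36, FastQC, HISAT2, SAMtools and StringTie 2.1.3 with the genome build GRCm38.p5, per the submitters' processing notes, which give no order or settings. The annotation release, the strand setting and any filter or pooling are not given in the sources used here.

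The authors deposited a single table of TPM per gene, with Ensembl gene identifiers, symbols, types and coordinates for 51912 genes. All columns have the same sum to within rounding, and the deposited TPM hold 0.0001 in place of 0, for 24194 to 28825 genes per library. TPM keep no read depth, so the depth and the counting precision of each library are unknown, and the precision given is the spread between libraries. All 12 columns matched a sample title. Of the gene identifiers, 51633 are also in GENCODE M21, 48615 of these (94.15%) with the same coordinates and 47577 with the same symbol. The coordinates printed are those of the deposited table. A gene name is carried by more than 1 row for 98 names.

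Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), for the 15623 genes with a mean TPM of at least 1 over the 12 libraries. A single fit had 1 mean per group, so that the 4 groups shared an estimate of the spread. The comparisons were erinacine S against DMSO at 16 h and at 48 h, their difference (the interaction), and 48 h against 16 h in DMSO and in erinacine S. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A fold change is on the log2(TPM + 1) scale, which understates the change of low genes. A gene was called non-overlapping where the 3 libraries of a group all lay on the same side of the other 3. The erinacine S effects at both times were compared by Pearson's r across genes.

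Before the data were examined, 29 gene lists with 651 members were fixed from general knowledge: pathways tied to the title of the series (cholesterol, neurosteroid and fatty acid synthesis, sterol uptake and export, neurotrophins, axon regeneration, neurite growth, synapse), activity and stress responses, energy metabolism, extracellular matrix and markers of the cell types a cortical culture can hold. The table has no row for 2 of the symbols, Hsd17b8 and Sts. The 26 lists with at least 5 measured members were tested with camera (limma) with a preset correlation between genes of 0.01, which compares the genes of a list with all others, adjusted over the lists within a comparison. The same test with a correlation estimated from the data, and fry (limma), whose PValue tests whether the genes of a list move, on balance, in a single direction without comparing them with other genes, were run as alternatives. Counts called adjusted over the list alone use the Benjamini-Hochberg adjustment within the list. The score of a list in a library is the median log2 difference of its members from the DMSO mean of the same time.

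Also before the data were examined, the main fits, the alternatives and the rule for named genes were fixed. The rule takes, for each main comparison, the 8 largest rises and 8 largest falls among genes that passed with non-overlapping libraries, leaving out gene models with no given name, and where fewer than 8 passed, the 5 with the smallest p instead. It adds up to 4 members with the smallest p for each list that passed or had 3 or more called members and for the cholesterol and neurosteroid synthesis lists, and the 5 genes with the smallest p of the interaction. The text gives part of the genes so named, and 1 of them is not reported here. The alternatives were a pseudocount of 0.1 or 5, no filter on low values or a mean TPM of at least 5, median-ratio scaling, quantile normalization, TPM recomputed without mitochondrially encoded genes, the replicate number as a block, robust eBayes, library weights, only the libraries compared, the other list tests and leaving out each library in turn. Chosen after the data were seen were a replicate block within each time, TPM recomputed also without the 6 abundant nuclear copies of mitochondrial genes, and the emphasis on the fit without erinacine S 48 h replicate 1.

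Replicates were compared before averaging. Across genes, log2 values correlated at 0.987 to 0.990 in DMSO 16 h, 0.985 to 0.995 in erinacine S 16 h, 0.993 to 0.995 in DMSO 48 h and 0.980 to 0.995 in erinacine S 48 h, and at most 0.173% of the tested genes had identical values in a pair of libraries. At 16 h the deviations of same-numbered libraries from their group means correlated at 0.480, 0.185 and 0.510 for replicates 1, 2 and 3. Each was over 0.1 and highest for its own number, so the numbers may pair the libraries at that time. The pairing is read from these values, since the labels give none, and 3 libraries per group are too few to establish it. Principal component 1 took 54.6% of the variance and parted 16 h from 48 h, and component 2 took 12.8%, with erinacine S 48 h replicate 1 at -35.1 and all others between -11.3 and 12.2.

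The fits were tested on simulated data with 200 changed genes among 15623, with the real means and spread. Of genes changed by 0.5, 1 and 2 on the log2 scale, the 16 h comparison recovered 50.8%, 84.1% and 97.3%, the 48 h comparison 54.0%, 90.5% and 95.9% and the comparison over time in DMSO 52.4%, 88.9% and 95.9%, with 9, 12 and 8 false calls among the 15423 unchanged genes. In simulated lists the shifted list passed by all 3 list tests and none of the 25 others did. The simulated genes varied independently of each other, without paired libraries or an outlying library. In the real data the estimated correlation within a list ranged from -0.011 (axon regeneration) to 0.906 (dividing cells). The simulation therefore does not give the rate of false calls for correlated genes or lists. The difference between times and the change over time in erinacine S were not simulated. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.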

Results

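RNA from primary cortical neurons of C57BL/6J mouse embryos (E17.5) was sequenced after 16 h or 48 h in culture with DMSO, the solvent control, or with 1 µg/mL erinacine S, a compound from the mycelium of the mushroom Hericium erinaceus. The 12 libraries fall into 4 groups of 3: DMSO 16 h, erinacine S 16 h, DMSO 48 h and erinacine S 48 h. The labels call the 3 libraries of a group independent repeats and do not say which litters, dishes or days these stand for, so each p-value measures the spread between these libraries, which may be technical. The title of the series places the study in neuronal regeneration and neurosteroid accumulation. Expression was deposited as TPM, transcript abundance scaled to the same total in each library, for 51912 genes with coordinates on GRCm38, and the read depth of each library is unknown. Between 15219 and 15789 genes reached 1 TPM in a library. The mitochondrially encoded genes took 7.24% to 7.70% of the TPM in the 16 h libraries and 5.12% to 7.32% in those of 48 h, lowest in erinacine S 48 h replicate 1.

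The clearest response to erinacine S was seen at 48 h in the immediate early genes, which neurons switch on within minutes of electrical activity. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), a subunit of the transcription factor AP-1, fell from 33.6 ± 1.47 TPM in DMSO to 5.67 ± 1.58 TPM with erinacine S (SD, n = 3 each), a log2 fold change of -2.40 ± 0.19 (SE; limma, adjusted p = 0.000574). The nuclear receptor Nr4a1 (ENSMUSG00000023034, chromosome 15, 101266846 to 101274792) fell from 40.6 ± 2.59 to 10.4 ± 2.61 TPM, and the neuronal activity factor Npas4 (ENSMUSG00000045903, chromosome 19, 4984355 to 4989971) fell from 38.4 ± 0.453 to 12.02 ± 2.59 TPM (SD, n = 3 each). Their log2 fold changes were -1.89 ± 0.16 and -1.61 ± 0.16 (SE; adjusted p = 0.000664 and 0.00135). Of the 27 measured immediate early genes, 10 fell, none rose and 17 did not pass over all genes, and 18 fell when adjusted over the list alone. The AP-1 subunits Jun and Junb fell by 1.31 and 1.24 on the log2 scale. The list as a whole fell, with a median log2 fold change of -0.75 (adjusted p = 2.2e-35), and kept its call with an estimated correlation (adjusted p = 0.000552).

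**Figure D1:**
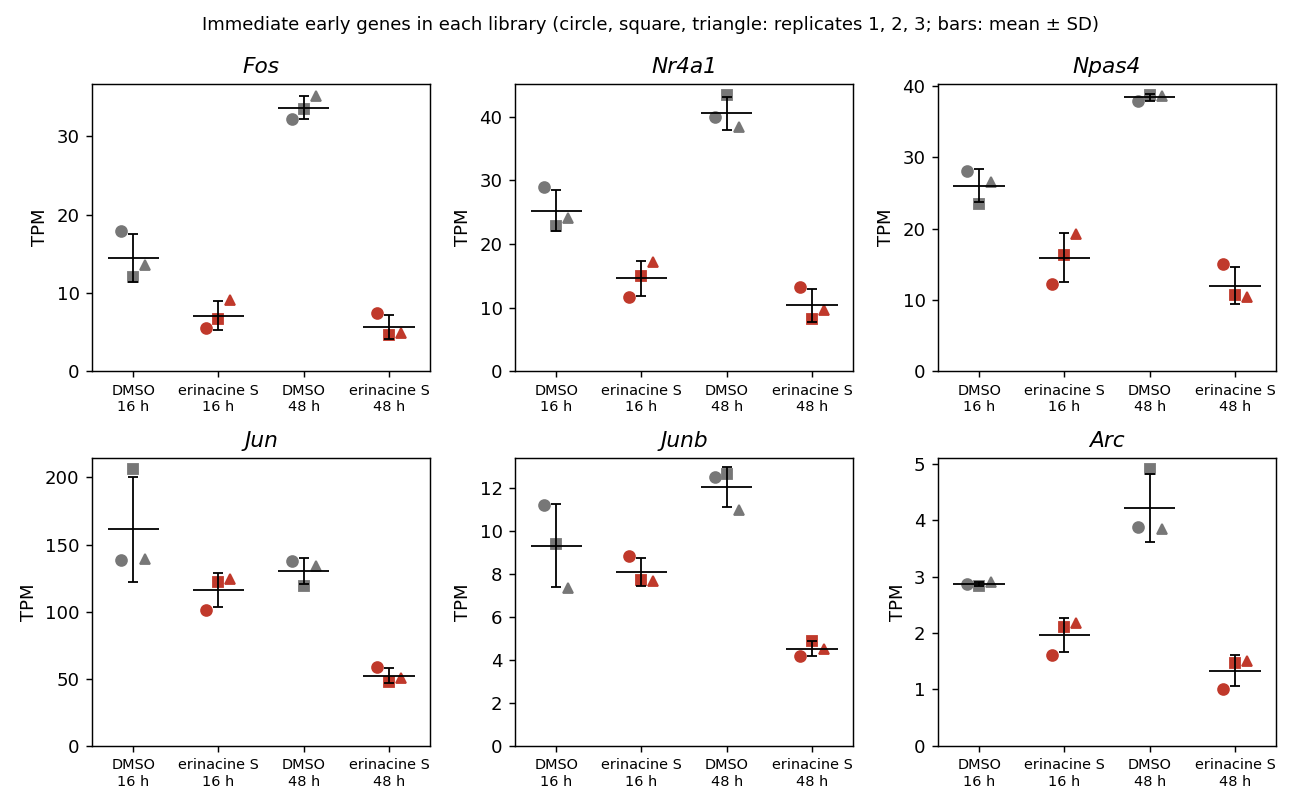
TPM of 6 immediate early genes (y axes, TPM from 0) in each of the 12 libraries, by group (x axes), with the mean and SD of each group (n = 3) as bars; grey marks are DMSO, red marks erinacine S. At 48 h every erinacine S library lay below every DMSO library for all 6 genes, and Fos averaged 5.67 TPM against 33.6 TPM.

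Outside the activity genes, 3 genes rose at 48 h. Cxcr4 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293), the receptor for the chemokine Cxcl12, rose from 17.1 ± 0.814 to 28.5 ± 1.29 TPM (SD, n = 3 each; log2 fold change 0.70 ± 0.08, SE, adjusted p = 0.00215). Ackr3, which binds the same chemokine, rose by 0.59 ± 0.10 on the log2 scale and the membrane protein gene Tmem150c by 0.47 ± 0.08 (SE; adjusted p = 0.0458 and 0.0413). Sema4a, a semaphorin, and Lsm5, which takes part in RNA splicing and decay, did not pass (log2 fold changes 0.68 and 1.09, adjusted p = 0.0564 and 0.0605). Crh (ENSMUSG00000049796, chromosome 3, 19693401 to 19695396), which encodes corticotropin-releasing hormone, fell from 3.90 ± 0.865 to 0.177 ± 0.201 TPM (log2 fold change -2.06 ± 0.22, SE, n = 3 each, adjusted p = 0.00201). The annexin Anxa3 fell by 1.78 and osteopontin, encoded by Spp1, by 1.84 on the log2 scale. The neuropeptide precursor Vgf fell by 0.90 and the stress-induced transcription factor Atf3 by 0.91. Egr1, Arc, Ier2, Dusp5 and Dusp1 of the immediate early list also fell. So did the dystrobrevin gene Dtna and the imprinted noncoding RNA gene Peg13. These falls were of 0.33 to 1.33 on the log2 scale, and all of these genes but Egr1 are named after their values were seen.

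Cholesterol synthesis enzymes had higher values with erinacine S at 48 h, while genes of neurosteroid synthesis, the subject in the title, had values of both signs. All 20 cholesterol synthesis enzymes had positive log2 fold changes, with a median of 0.31. None passed over all genes, and 8 rose when adjusted over the list alone. The sterol desaturase Sc5d had a log2 fold change of 0.44 ± 0.09 (SE, n = 3 each; 88.8 ± 4.82 TPM in DMSO and 121 ± 13.2 with erinacine S, SD; adjusted p = 0.144). Values were 0.56 ± 0.15 for Nsdhl, 0.47 ± 0.13 for Fdps and 0.50 ± 0.15 for Dhcr7, which makes cholesterol in the last step of its route (SE). The list rose by the preset test (adjusted p = 7.27e-11), but not with an estimated correlation (adjusted p = 0.356). Its median log2 difference from the DMSO mean was 0.57 in erinacine S 48 h replicate 1 and 0.16 and 0.17 in the other libraries of that group, and without replicate 1 the median log2 fold change was 0.16 (adjusted p = 3.97e-06). None of the 17 measured neurosteroid synthesis genes passed at 48 h (limma; median log2 fold change -0.01, adjusted p of the list 0.617). The largest by p were Cyb5a at 0.16 ± 0.08, Hsd17b12 at -0.18 ± 0.10, Fdx1 at -0.18 ± 0.10 and Por at 0.12 ± 0.07 (SE).

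**Figure D2:**
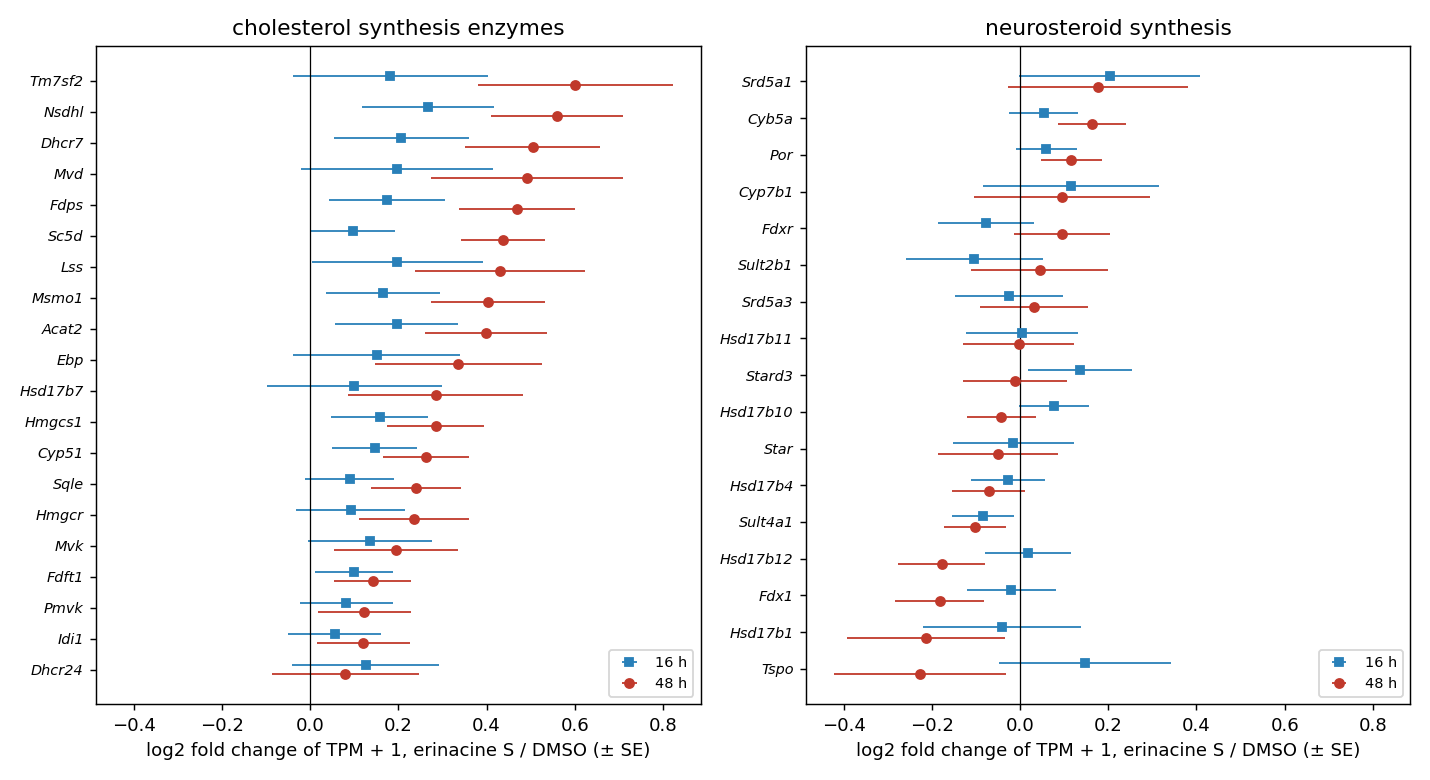
Log2 fold change of TPM + 1 with erinacine S against DMSO (x axes, ± SE, n = 3 per group) for the 20 cholesterol synthesis enzymes and the 17 measured neurosteroid synthesis genes (y axes), at 16 h in blue and 48 h in red. The cholesterol enzymes lie above 0 at both times, with medians of 0.15 and 0.31, and the neurosteroid genes lie on both sides, with medians of 0.00 and -0.01.

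Lipid, growth factor and regeneration lists at 48 h went in different directions. Of 17 fatty acid synthesis genes, none passed over all genes, while 8 rose and 1 fell when adjusted over the list alone. Examples were the desaturase gene Scd2 at 0.40 ± 0.10, the malic enzyme Me1 at 0.26 ± 0.07 and the elongase Elovl1 at 0.37 ± 0.10 (SE). The list rose by the preset test (median 0.21, adjusted p = 3.73e-05; adjusted p = 0.408 with an estimated correlation). Among 15 neurotrophins and their receptors only Vgf fell over all genes, and 3 fell when adjusted over the list alone. Brain-derived neurotrophic factor, Bdnf, had a log2 fold change of -1.04 ± 0.21 and the growth factor Igf1 of -0.82 ± 0.17 (SE; adjusted p = 0.105 and 0.112). The list fell by the preset test (median -0.14, adjusted p = 0.00206; adjusted p = 0.316 with an estimated correlation), with medians of -0.29 without erinacine S replicate 1, -0.045 without replicate 2 and -0.09 without DMSO replicate 3. Of 26 axon regeneration-associated genes, Jun and Atf3, both induced by axon injury, fell over all genes, and 4 fell when adjusted over the list alone. The neuropeptide gene Adcyap1 stood at -1.13 ± 0.21 and Klf9, a transcription factor that restrains axon growth, at -1.59 ± 0.33 (SE; adjusted p = 0.0765 and 0.132). That list fell too (median -0.05, adjusted p = 0.00391; adjusted p = 0.102 with an estimated correlation), with a median of -0.09 without DMSO replicate 1 or erinacine S replicate 1 and of -0.03 without DMSO replicate 3. Neither the 40 neurite growth genes (median 0.01, adjusted p = 0.768) nor the 41 synapse genes (median 0.07, adjusted p = 0.501) passed. Without erinacine S 48 h replicate 1 the synapse list fell by the preset test (median -0.09, adjusted p = 0.000403). With all libraries and an estimated correlation the synapse list had adjusted p = 0.940.

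Markers of dividing cells, radial glia and astrocytes were lower with erinacine S at 48 h, and they moved with a single library. In erinacine S 48 h replicate 1 the astrocyte transporter Slc1a3 was at 21.2 TPM, against 53.1 to 74.1 TPM in the other 5 libraries of that time. The proliferation marker Mki67 was at 5.46 TPM against 16.7 to 21.2 TPM, and the oligodendrocyte lineage factor Olig1 at 20.5 TPM against 91.5 to 135 TPM. The lists for dividing cells (median -0.46, adjusted p = 2.39e-08), radial glia and intermediate progenitors (median -0.30, adjusted p = 0.00157) and astrocytes (median -0.27, adjusted p = 0.0331) fell by the preset test. They had adjusted p = 0.525, 0.549 and 0.549 with an estimated correlation. None of their 25, 13 and 10 measured members passed, among them Mcm5 at -0.57 ± 0.23 and Vim at -0.53 ± 0.21 (SE). Without erinacine S 48 h replicate 1 their medians were -0.01, 0.07 and 0.04 and none of the lists passed (adjusted p = 0.703, 0.689 and 0.703). Without replicate 2 or 3 of that group the medians were -0.46 and -0.53 for radial glia and -0.43 and -0.47 for astrocytes. The astrocyte call also ended without DMSO 48 h replicate 1 or 2 (adjusted p = 0.0947 and 0.0584).

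Microglial and oligodendrocyte lineage markers were lower in all 3 erinacine S libraries of 48 h. Of 9 microglia and macrophage genes, the complement gene C1qc fell (log2 fold change -1.48 ± 0.24, SE, adjusted p = 0.0413), and 5 fell when adjusted over the list alone. C1qa stood at -1.66 ± 0.29 and Ctss, a lysosomal protease, at -1.23 ± 0.31 (SE; adjusted p = 0.0564 and 0.216). The median log2 difference of this list from the DMSO mean was -1.91, -0.999 and -0.54 in erinacine S replicates 1, 2 and 3. The list fell by the preset test (median -1.23, adjusted p = 9e-08; adjusted p = 0.288 with an estimated correlation), and without replicate 1 its median was -0.77. None of the 10 oligodendrocyte lineage genes passed, with Sox10 at -0.69 ± 0.21 and Pdgfra at -0.42 ± 0.17 (SE). That list fell (median -0.39, adjusted p = 3.15e-05; adjusted p = 0.119 with an estimated correlation). None of the 21 extracellular matrix genes passed, with Bgn at -0.89 ± 0.30 and Ctgf at -0.88 ± 0.35 (SE). The matrix list fell (median -0.37, adjusted p = 3.15e-05; adjusted p = 0.288 with an estimated correlation), and its median without replicate 1 was -0.14 (adjusted p = 0.0168).

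**Figure D3:**
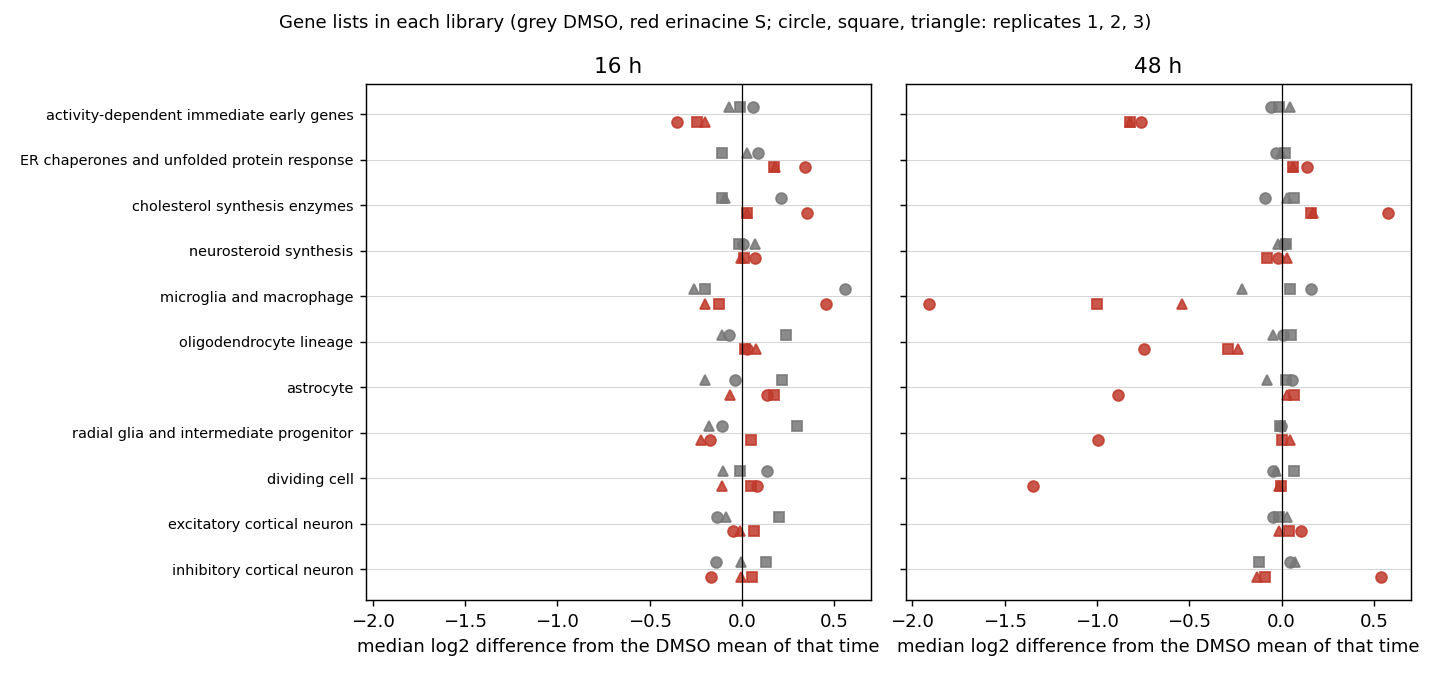
Median log2 difference of each gene list from the DMSO mean of the same time (x axes) for 11 lists (y axis) in each library, at 16 h and 48 h; grey marks are DMSO, red marks erinacine S, and circles, squares and triangles are replicates 1, 2 and 3. At 48 h the immediate early genes lie between -0.82 and -0.76 in the erinacine S libraries, while dividing cell markers lie at -1.35 in replicate 1 and at -0.01 and -0.02 in the others.

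Smaller shifts at 48 h were seen in other lists. The 39 nuclear-encoded oxidative phosphorylation genes, among them Uqcrc1 at -0.26 ± 0.06 and Atp5b at -0.24 ± 0.07 (SE), had a median of -0.08 with none past the threshold over all genes and 1 lower when adjusted over the list alone. That list fell by the preset test (adjusted p = 3.15e-05; adjusted p = 0.544 with an estimated correlation), with a median of -0.05 without erinacine S replicate 2. The 26 NRF2 targets of the antioxidant response (median 0.10, adjusted p = 0.0126) and the 22 ER chaperones and unfolded protein response genes (median 0.11, adjusted p = 0.0202) rose, each with adjusted p = 0.566 with an estimated correlation. Pgd, of the pentose phosphate pathway, stood at 0.22 ± 0.06 and the ER protein disulfide isomerase Pdia4 at 0.20 ± 0.06 (SE). The NRF2 median was 0.21 without erinacine S replicate 1, and its call ended without DMSO replicate 3 or erinacine S replicate 2 or 3 (adjusted p = 0.058, 0.169 and 0.427), and the ER call without DMSO replicate 1 or erinacine S replicate 1 (adjusted p = 0.0555 and 0.169). The 21 interferon response genes fell (median -0.17, adjusted p = 0.0331; adjusted p = 0.549 with an estimated correlation), with B2m at -0.66 ± 0.31 and Stat2 at 0.33 ± 0.12 (SE). That call ended without DMSO replicate 2 (adjusted p = 0.2) or erinacine S replicate 1 (adjusted p = 0.703), and with median-ratio scaling (adjusted p = 0.0572). The integrated stress response did not pass with all libraries (median -0.06, adjusted p = 0.116, and adjusted p = 0.734 with an estimated correlation). It fell by the preset test without erinacine S replicate 1 (median -0.17, adjusted p = 4.16e-05).

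Of the 15623 genes tested at 48 h, 21 passed, 3 higher and 18 lower, 1400 had an unadjusted p under 0.05, and all 21 had no overlap between the groups. Non-overlapping values were seen in 19.3% of all genes tested, where chance gives 10%. Of the 26 lists tested, 4 rose and 11 fell by the preset test, and only the immediate early genes passed with an estimated correlation. The count of genes was 114 without erinacine S 48 h replicate 1 (7 higher and 107 lower, the 21 included), 13 without replicate 2 or 3 of that group, 9 without DMSO 48 h replicate 1 or 3 and 10 without replicate 2. Fos, Nr4a1, Npas4, Jun, Junb, Arc, Anxa3, Crh and Cxcr4 passed without any of these 6 libraries, and the other called genes lost their calls without at least 1. The count was 1599 with a weight estimated for each library and 12 with only the 6 libraries compared. With a pseudocount of 0.1, Crh (adjusted p = 0.0599), Spp1, C1qc, Egr1 and Dtna did not pass.

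Among the 26 tested lists at 16 h, the ER chaperones had the highest median with erinacine S and the immediate early genes the lowest. Calreticulin, encoded by Calr (ENSMUSG00000003814, chromosome 8, 84841850 to 84846934), had 452 ± 47.2 TPM in DMSO and 590 ± 30.4 TPM with erinacine S (SD, n = 3 each; log2 fold change 0.39 ± 0.08, SE). The chaperones Hsp90b1 and Hspa5, which fold proteins in the ER, stood at 0.37 ± 0.08 and 0.38 ± 0.10, and Pdia4 at 0.29 ± 0.06 (SE). Of the 22 measured ER chaperones and unfolded protein response genes 20 had positive values, none passed over all genes and 11 rose when adjusted over the list alone. The list rose (median 0.22, adjusted p = 1.92e-29), also with an estimated correlation (adjusted p = 0.027). With the replicate as a block within each time and an estimated correlation it did not pass (adjusted p = 0.146). Fos had a log2 fold change of -0.94 ± 0.19 (14.5 ± 3.07 against 7.10 ± 1.87 TPM, SD, n = 3 each), Nr4a1 of -0.76 ± 0.17 and Npas4 of -0.69 ± 0.16 (SE). Of the 27 immediate early genes 25 had negative values, none passed over all genes and 3 fell when adjusted over the list alone. That list fell (median -0.25, adjusted p = 2.39e-19, and adjusted p = 0.00513 with an estimated correlation). Under the block within each time and an estimated correlation it had adjusted p = 0.151.

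The sterol and stress lists at 16 h had smaller medians and lost their calls with an estimated correlation. The 20 cholesterol synthesis enzymes all had positive values (median 0.15), among them Nsdhl at 0.27 ± 0.15, Hmgcs1, which starts the mevalonate route, at 0.16 ± 0.11, Cyp51 at 0.15 ± 0.10 and Acat2 at 0.20 ± 0.14 (SE). The list rose by the preset test (adjusted p = 9.73e-07; adjusted p = 0.626 with an estimated correlation). The 17 neurosteroid synthesis genes did not pass (limma; median 0.00, adjusted p = 0.817), with the translocator Stard3 at 0.14 ± 0.12, Srd5a1, which reduces progesterone, at 0.20 ± 0.20, Hsd17b10 at 0.08 ± 0.08 and Sult4a1 at -0.08 ± 0.07 (SE). The sign of Srd5a1 turned without erinacine S replicate 1 and that of Hsd17b10 without DMSO replicate 2. The 17 fatty acid synthesis genes rose (median 0.12, adjusted p = 9.28e-07; adjusted p = 0.374 with an estimated correlation), with Scd1 at 0.33 ± 0.15 and Scd2 at 0.24 ± 0.10 (SE). The 26 NRF2 targets (median 0.10, adjusted p = 0.000236), with catalase, Cat, at 0.11 ± 0.06, and the 21 interferon response genes (median 0.12, adjusted p = 0.00347), with Rsad2 at 0.28 ± 0.13, rose too (SE). With an estimated correlation they had adjusted p = 0.626 and 0.613. The 31 integrated stress response genes (median -0.07, adjusted p = 0.000213), with Psph at -0.19 ± 0.11, and the 26 axon regeneration-associated genes (median -0.04, adjusted p = 0.018), with Jun at -0.45 ± 0.14 and Basp1 at -0.12 ± 0.09, fell (SE). With an estimated correlation they had adjusted p = 0.626 and 0.127. None of the members of these 7 lists passed over all genes or when adjusted over its list alone.

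No gene passed at 16 h (limma): 201 of 15623 had an unadjusted p under 0.05, where chance gives 781, and 4.19% had no overlap between the groups, where chance gives 10%. The smallest adjusted p, 0.834, was that of Ttll7 (log2 fold change -0.82 ± 0.13, SE), a tubulin-modifying enzyme that stood at 15.1 ± 0.531 TPM in DMSO and 8.11 ± 0.471 TPM with erinacine S (SD, n = 3 each). Next by p in that direction were Spr, which makes the cofactor tetrahydrobiopterin, at -0.44 ± 0.09 and the mitochondrial tRNA gene mt-Tp at -0.88 ± 0.20, and in the other direction Rpa1, which binds single-stranded DNA, stood at 0.36 ± 0.09 (SE). Without a filter on low values 2 genes passed. Of 26 lists, 5 rose and 3 fell by the preset test. Replicates with the same number deviated together at 16 h. Under the block within each time, chosen after the data were seen, none of the lists passed with an estimated correlation. Radial glia and intermediate progenitor genes fell under it by the preset test (adjusted p = 0.0322 against 0.115 without the block). The planned replicate block gave 8 lists by the preset test, 5 higher and 3 lower. Without erinacine S replicate 1 only 3 lists passed by the preset test, and the cholesterol (adjusted p = 0.569), fatty acid (0.235), NRF2 (0.971), interferon (0.256), integrated stress (0.298) and axon regeneration (0.139) calls ended. Calls also ended without DMSO replicate 2 for cholesterol synthesis (adjusted p = 0.0767), integrated stress (0.196) and interferon (0.612), without DMSO replicate 3 for fatty acid synthesis (0.0721), NRF2 (0.0896), integrated stress (0.142) and axon regeneration (0.272), without erinacine S replicate 2 for axon regeneration (0.343) and without replicate 3 for interferon (0.0679). Without DMSO replicate 1 the medians were 0.26 for cholesterol synthesis, 0.18 for NRF2, 0.21 for interferon, -0.14 for integrated stress and -0.07 for axon regeneration. The cholesterol median was 0.07 without DMSO replicate 3, the interferon median 0.20 without DMSO replicate 3 or erinacine S replicate 2, and the axon regeneration median -0.07 without erinacine S replicate 3. With an estimated correlation the ER call ended without any single library except DMSO replicate 1 (adjusted p between 0.0557 and 0.197), and the immediate early call without DMSO replicate 2 (adjusted p = 0.0688).

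With all libraries the remaining lists passed at neither time. Some passed by the preset test under an alternative. At 16 h cholesterol uptake rose (adjusted p = 0.00559) and inhibitory neurons fell (0.0164) without DMSO replicate 1. Excitatory neurons rose without DMSO replicate 2 (0.0436), and heat shock without DMSO replicate 3 (0.0107) or erinacine S replicate 1 (0.00696). Cholesterol uptake rose at 48 h under the block within each time (0.0352). With an estimated correlation these had adjusted p between 0.297 and 0.833. At 16 h and 48 h the medians were 0.07 and 0.05 for cholesterol uptake and SREBP control (adjusted p = 0.187 and 0.084), 0.05 and -0.14 for LXR targets and cholesterol export (0.821 and 0.173) and -0.00 and -0.01 for the heat shock response (0.274 and 0.912). They were 0.00 and 0.01 for p53 targets and cell death (0.826 and 0.912), 0.05 and -0.03 for glycolysis and hypoxia (0.144 and 0.464), -0.03 and 0.01 for excitatory cortical neurons (0.826 and 0.912) and 0.01 and -0.01 for inhibitory cortical neurons (0.581 and 0.66). Median, mean and test differed in sign for the heat shock, p53, excitatory and inhibitory neuron lists at both times and for the neurotrophin and microglia lists at 16 h. Endothelial, fibroblast and red blood cell markers had 1, 4 and 4 measured members and were not tested, with medians of 0.41, 0.01 and 0.40 at 16 h and 0.17, -0.10 and 0.68 at 48 h.

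The effect of erinacine S differed between 48 h and 16 h for the immediate early genes as a list. The median difference, 48 h less 16 h, was -0.67 on the log2 scale (adjusted p = 2.72e-22; adjusted p = 0.00296 with an estimated correlation). Junb (-1.07 ± 0.19) and Fos (-1.46 ± 0.27) had among the smallest p of single genes, with Anxa3 (-1.44 ± 0.26), Crh (-1.59 ± 0.31) and Spp1 (-2.08 ± 0.40, SE). No gene passed (limma; smallest adjusted p = 0.72), and 432 had an unadjusted p under 0.05. Cholesterol synthesis enzymes rose more at 48 h by the preset test (median difference 0.18, adjusted p = 0.000178), but not with an estimated correlation (adjusted p = 0.596). The list's score at 48 h was 0.57 in erinacine S replicate 1 and 0.16 and 0.17 in the others, so replicate 1 could carry much of this difference. Across the 15623 genes, which are not independent replicates, the log2 fold changes at 16 h and 48 h had a Pearson r of 0.197 (covariance 0.00538) with no library in common. In 400 regroupings of the libraries within each time the median absolute r was 0.0702. Without DMSO 16 h replicate 2 r was 0.0763, without erinacine S 16 h replicate 3 it was 0.121, and over the 12 libraries left out in turn it reached 0.253.

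From 16 h to 48 h in DMSO, the synapse, neurite growth and neurotrophin lists rose and the interferon and integrated stress response lists fell by the preset test. Of 41 synapse genes 29 rose and 2 fell, and 30 and 2 when adjusted over the list alone. Examples were the calcium-dependent kinase gene Camk2b at 0.98 ± 0.12, the NMDA receptor subunit Grin2a at 1.51 ± 0.18 and the fusion regulator Cplx1 at 0.78 ± 0.10 (SE, n = 3 each; adjusted p = 0.000131, 0.000134 and 0.000285). Of 40 neurite growth genes 22 rose and 2 fell (25 and 2 over the list alone), among them Mapt, which encodes tau, at 0.66 ± 0.09 and Ncam1 at 0.62 ± 0.10 (SE). Of 15 neurotrophin genes 7 rose, also over the list alone, with the receptor Ntrk2 at 1.37 ± 0.14 and Vgf at 0.92 ± 0.14 (SE). These lists rose by the preset test (medians 0.47, 0.32 and 0.47, adjusted p = 1.5e-09, 5.38e-07 and 0.00124). They had adjusted p = 0.375, 0.333 and 0.266 with an estimated correlation. All 21 interferon response genes had negative values and 17 fell (18 over the list alone), among them the chemokine Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), with 16.4 ± 3.02 TPM at 16 h and 0.239 ± 0.132 TPM at 48 h (SD, n = 3 each; log2 fold change -3.80 ± 0.17, SE, adjusted p = 2.54e-07). Isg15 fell by 3.06 ± 0.23, Rsad2 by 2.63 ± 0.13 and Oasl2 by 2.15 ± 0.17 on the log2 scale (SE). Of 31 integrated stress response genes 21 fell and none rose (25 and 1 over the list alone), with Ddit3 at -1.03 ± 0.11 and Atf5 at -1.06 ± 0.12 (SE). The medians of both lists were -1.54 and -0.56 (adjusted p = 9.67e-14 and 1.5e-09; adjusted p = 0.121 and 0.266 with an estimated correlation).

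The oligodendrocyte lineage, astrocyte, ER chaperone, oxidative phosphorylation and glycolysis lists also rose with time in DMSO by the preset test. Of 10 oligodendrocyte lineage genes 9 rose, also over the list alone, with Pdgfra at 1.65 ± 0.17 and Sox10 at 1.54 ± 0.21 (SE), and 3 of 10 astrocyte genes rose (7 over the list alone). Of 22 ER chaperones 14 rose and none fell (14 and 1 over the list alone), with Hspa5 at 0.67 ± 0.10. Of 39 oxidative phosphorylation genes 13 rose, also over the list alone, with Uqcrfs1 at 0.56 ± 0.07. Of 26 glycolysis and hypoxia genes 11 rose and 3 fell (12 and 3 over the list alone), with hexokinase Hk1 at 0.45 ± 0.06 and Vegfa at -1.08 ± 0.09 (SE). Medians were 1.35, 0.61, 0.29, 0.19 and 0.18 (adjusted p = 1.91e-05, 0.00615, 7.04e-05, 0.00131 and 0.0178). With an estimated correlation they had adjusted p = 0.143, 0.461, 0.375, 0.591 and 0.143. Of 17 fatty acid synthesis genes 8 rose and 2 fell, also over the list alone, with Me1 at 0.57 ± 0.07, and of 10 LXR targets 4 rose, also over the list alone, with the cholesterol hydroxylase Cyp46a1 at 1.23 ± 0.13 (SE). Of 27 immediate early genes 9 rose and 3 fell (12 and 4 over the list alone), with Inhba at 1.28 ± 0.12 and Ier3 at -1.18 ± 0.21 (SE). Their medians were 0.28, 0.44 and 0.28 (adjusted p = 0.0223, 0.0342 and 0.0398; adjusted p = 0.591, 0.252 and 0.375 with an estimated correlation). These 3 calls ended without DMSO 16 h replicate 3 (adjusted p = 0.0824 each), the immediate early call also without DMSO 48 h replicate 3 (0.0687) and with a pseudocount of 0.1 (0.0573), the LXR call without a filter on low values (0.302), and the oxidative phosphorylation call without DMSO 16 h replicate 2 (0.0643).

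**Figure D4:**
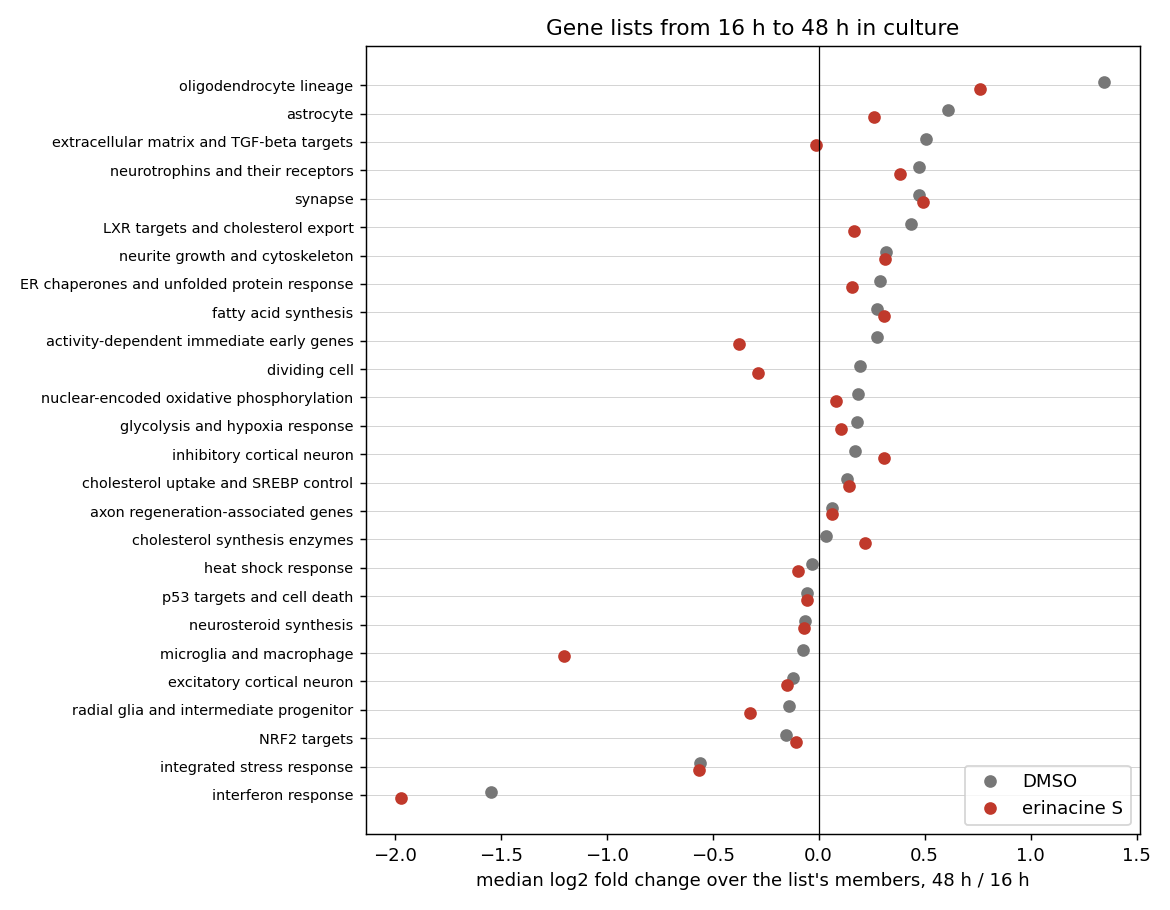
Median log2 fold change from 16 h to 48 h (x axis) over the measured members of each of the 26 tested gene lists (y axis), in DMSO (grey) and in erinacine S (red). The interferon response has the lowest medians, -1.54 and -1.97, the oligodendrocyte lineage the highest, 1.35 and 0.76, and the immediate early genes lie at 0.28 in DMSO and -0.38 in erinacine S.

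The largest single rises with time in DMSO were those of Klf9 (ENSMUSG00000033863, chromosome 19, 23141226 to 23166911), from 4.87 ± 0.704 to 39.6 ± 7.26 TPM (SD, n = 3 each; log2 fold change 2.78 ± 0.33, SE, adjusted p = 0.000144), the potassium channel gene Kcnk9 at 2.51 ± 0.23 and the Ras exchange factor Rasgrf2 at 2.34 ± 0.14 (SE). The chemokine Cxcl14, the Wnt inhibitor Wif1, the matrix gene Frem2 and the adenylate cyclase Adcy1 rose by 2.15 to 2.30. The keratin gene Krt14 rose by 2.58 ± 0.79 (SE; adjusted p = 0.0263), with adjusted p between 0.0543 and 0.0764 when any DMSO library other than 16 h replicate 2 was left out. The largest falls included the calcium-binding protein genes S100a6, from 30.2 ± 6.78 to 1.26 ± 0.828 TPM (SD, n = 3 each; log2 fold change -3.82 ± 0.30, SE, adjusted p = 1.22e-05), and S100a4 at -3.59 ± 0.28. Ccl5, a chemokine, fell by 3.01, Bst2, an antiviral membrane protein gene, by 2.77 and Fam159b by 2.76 on the log2 scale. Prl2c2, whose values are uncertain because it has near-identical copies, had 21.03, 16.3 and 23.4 TPM at 16 h and was listed at the value in place of 0 in all 48 h libraries. Cholesterol synthesis enzymes (1 rose, Pmvk, and 1 fell, Fdft1; median 0.03, adjusted p = 0.703) and neurosteroid genes (1 rose, Sult4a1, and 2 fell, Tspo and Hsd17b11; median -0.07, adjusted p = 0.703) did not pass as lists.

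Among lists that did not pass in DMSO over time, 4 or more members were called in the axon regeneration (7 rose, 5 fell), NRF2 (1 rose, 4 fell), heat shock (3 rose, 2 fell), p53 (2 rose, 3 fell), extracellular matrix (7 rose, 2 fell), radial glia and intermediate progenitor (2 rose, 3 fell), excitatory neuron (2 rose, 5 fell) and inhibitory neuron lists (2 rose, 2 fell). Adjusted over the list alone, 9 axon regeneration genes rose and 5 fell, and the other counts were the same. Median, mean and test differed in sign for the heat shock and p53 lists. The intermediate progenitor factor Eomes fell by 1.76 and the deep-layer factor Fezf2 by 1.36 on the log2 scale, and the interneuron protein gene Calb2 rose by 1.11. Over all genes 5107 changed, 2509 higher and 2598 lower, 6899 had an unadjusted p under 0.05, and 50.5% had no overlap between the groups, where chance gives 10%. The count was 3401 without DMSO 48 h replicate 1. By the preset test 11 lists rose and 2 fell, and none passed with an estimated correlation.

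With erinacine S 4783 genes changed from 16 h to 48 h, 2358 higher and 2425 lower. Synapse genes (30 rose, 1 fell; median 0.49), neurite growth genes (21 rose, 1 fell; median 0.32) and oligodendrocyte lineage genes (5 rose; median 0.76) rose as lists, and interferon response genes (18 fell; median -1.97) and integrated stress response genes (19 fell; median -0.57) fell (adjusted p = 2.68e-10, 7.13e-07, 0.00619, 2.36e-16 and 2.49e-09). Adjusted p = 0.406, 0.4, 0.4, 0.074 and 0.4 were found with an estimated correlation. Adjusted over the list alone, 32, 24 and 6 members of the first lists rose and 20 and 22 members of the last fell. Cholesterol synthesis (3 rose, 1 fell), fatty acid synthesis (6 rose), neurotrophin (4 rose) and ER genes (6 rose, 2 fell) rose as lists and microglia genes fell (4 fell), with adjusted p = 0.0298, 0.00312, 0.0326, 0.0326 and 0.00557, and with an estimated correlation adjusted p = 0.721, 0.566, 0.486, 0.719 and 0.566. Of the 27 immediate early genes 10 fell and 2 rose with erinacine S (median -0.38, adjusted p = 0.0145; adjusted p = 0.4 with an estimated correlation), also over the list alone, and the difference between treatments over time is the same contrast as the difference of the erinacine S effect between times. In both treatments 1879 genes rose and 1799 fell, where independent lists of these sizes would share 379 and 403, and Nr4a1 and Anxa3 passed in opposite directions. These comparisons share no library. The count with erinacine S was 3110 without erinacine S 16 h replicate 2 and 9338 with a weight estimated for each library.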

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

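Tests chosen only after their result was seen were the median of the immediate early genes without a library, the slower activity-regulated genes, all 3 tests of erinacine S 48 h replicate 1, and the regroupings of the gene counts and of the correlation between times.

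The immediate early genes drew attention because the erinacine S effect on the list differed between 48 h and 16 h by a median of -0.67 on the log2 scale (camera, adjusted p = 2.72e-22; adjusted p = 0.00296 with an estimated correlation), and because the list fell at 48 h. Technical and cellular sources were tested. A single library as the source was excluded, since without erinacine S 48 h replicate 1 the median was -0.82. A lower share of astrocytes and dividing cells as the whole source was argued against. With 58 markers of glial and dividing cells as a covariate, without the microglia list, the median was -0.79 and 15 members passed. At 48 h astrocyte and dividing cell markers were lower mainly in erinacine S replicate 1, so this adjustment is close to leaving that library out. In replicates 2 and 3 dividing cells lay at -0.01 and -0.02 and astrocytes at 0.07 and 0.03. The immediate early genes lay at -0.82 in both. The covariate brought the astrocyte and dividing cell medians to 0.09 and 0.03. It left microglia at -0.62 and the oligodendrocyte lineage at -0.18, so it covers a lower share of these cells only in part. A brief disturbance of the dishes at harvest would leave slower activity-regulated genes in place; the mean of 6 such genes outside the list and not called differed by -0.54 ± 0.17 at 48 h (SE), but these genes were chosen after the results were seen, so this source stays open. An effect of erinacine S and a difference in the handling of treated and control dishes over the 48 h also stay open, the last because no label records it.

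Erinacine S 48 h replicate 1 stands apart from the other 5 libraries of its time. A control dish under the wrong label was argued against by a single list, in a test chosen after the result was seen. The immediate early genes of this library lay at -0.76 from the DMSO mean. They lay at -0.82 in both other erinacine S libraries and at -0.06 to 0.04 in DMSO. Not all lists placed this library with the other erinacine S libraries: the NRF2 targets lay at -0.07, against 0.18 and 0.22. The library's cell type markers differed too, and the test does not take these into account. Fewer non-neuronal cells and nothing else was argued against too, because inhibitory neuron markers exceeded excitatory ones by 0.43 in this library, and by -0.13 to 0.09 in the others. A larger share of striatal neurons, from a dissection that took tissue under the cortex, may add to the difference: 13 of 14 striatal genes were higher, with a median difference of 0.80 from the other libraries, and Penk was at 46.8 TPM against 8.06 to 16.0, Adora2a at 59.1 against 11.3 to 19.3 and Drd2 at 33.7 against 9.99 to 14.9. What lowered the glial and dividing cell markers in the same library was not tested.

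The cholesterol synthesis enzymes drew attention because the erinacine S effect on the list was larger at 48 h than at 16 h by a median of 0.18 (camera, adjusted p = 0.000178; adjusted p = 0.596 with an estimated correlation). Over the 20 enzymes, the mean log2 level differed by 0.33 ± 0.15 at 48 h and by 0.15 ± 0.15 at 16 h (SE, n = 3 each). A shift of the whole list between dishes of a group could give such a value, since the difference at 48 h is little over 2 SE, and the 3 libraries per group are too few to decide. The single library erinacine S 48 h replicate 1 could also carry much of it, since the difference without it was 0.21 ± 0.15 (SE). With the markers of glial and dividing cells as a covariate the median was 0.17 against 0.31, so a shift of cell types, these sources and an effect of erinacine S on these enzymes all stay open.

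The erinacine S effect also differed between 48 h and 16 h in other lists by the test of the difference. The median difference was -0.13 for neurotrophins and their receptors (adjusted p = 0.00523; adjusted p = 0.272 with an estimated correlation), -0.14 for ER chaperones (2.85e-06; 0.272), -0.26 for the interferon response (0.000203; 0.272) and -0.073 for oxidative phosphorylation (0.00213; 0.657). It was -0.42 for the extracellular matrix (2.57e-05; 0.251), -0.30 for astrocytes (0.00931; 0.522), -0.51 for the oligodendrocyte lineage (2.85e-06; 0.103), -1.21 for microglia and macrophages (1.48e-07; 0.251) and -0.48 for dividing cells (6.45e-07; 0.529). In erinacine S 48 h replicates 1, 2 and 3 the median difference from the DMSO mean was -1.35, -0.01 and -0.02 for dividing cells, -0.89, 0.07 and 0.03 for astrocytes and -0.66, -0.02 and -0.31 for the extracellular matrix, so these differences rest largely or wholly on replicate 1.

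In 4 genes named by the rule all libraries of each comparison moved in opposite directions, and the difference was tested by the interaction. With erinacine S, Rsad2 and Dnajc3 were higher at 16 h and lower at 48 h than DMSO, with differences of -0.45 ± 0.19 and -0.28 ± 0.11 (SE). At 48 h Rsad2 was at 0.0696 to 0.157 TPM in DMSO and listed at the value in place of 0 in all 3 erinacine S libraries. From 16 h to 48 h, Anxa3 and Egr1 were higher in DMSO and lower with erinacine S, with differences of -1.44 ± 0.26 and -0.87 ± 0.30 (SE). None of the 4 passed (limma, adjusted p = 0.72 for Anxa3 and 1.00 for the others).

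Other splits of the same 6 libraries into 3 and 3 give 10 splits, too few for a share under 0.05. At 48 h the real split gave 21 genes and the highest other 1, and 15 lists against 15, which 2 splits reached. At 16 h it gave 0 genes and all 10 splits gave at least as many, and 8 lists against 13, with 5 splits as high. Of the other splits at 16 h, DMSO replicates 1 and 2 with erinacine S replicate 1 against the rest gave 698 genes, which points to a structure of these libraries other than treatment, while the 5 other splits that part a single numbered pair gave at most 1. Among the 4 splits that part all 3 numbered pairs, as the real one does, the highest other gave 0 genes and 4 lists. From 16 h to 48 h the real split gave 5107 genes in DMSO and 4783 with erinacine S against 0 in any other, reached by 1 split each, and 13 lists in DMSO against 12. For the difference between times, all 100 regroupings gave at least the 0 genes of the real groups, the highest 466. The correlation between times, 0.197, was reached by 1 of 200 regroupings, the real one, with 0.187 the highest other. It was also reached by 1 of the 80 that part all numbered pairs at 16 h, with 0.171 the highest other. These values argue against chance regrouping as its source. They do not exclude it, because the test was chosen after the value was seen and the margin is small. Without DMSO 16 h replicate 2 the correlation was 0.0763.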

How the results depend on the processing

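Leaving out a library was planned; the replicate block within each time was chosen after the data were seen. TPM keep no depth, so calls rest on the spread of 3 libraries per group. The count of genes at 48 h ranged from 9 to 114 over the libraries left out (21 with all), the lists at 16 h from 3 to 11 (8), the genes over time from 3401 to 4585 in DMSO (5107) and from 3110 to 4886 with erinacine S (4783), and the correlation between times from 0.0763 to 0.253 (0.197); fewer samples are part of these changes, and why the count rose to 114 without erinacine S 48 h replicate 1 was not tested. Library weights gave 1599 genes at 48 h (686 higher and 913 lower), 14 for the difference between times and 9338 over time with erinacine S; the cause was not tested. A pseudocount of 0.1 gave 1 gene for the difference between times, no filter 2 genes at 16 h, a mean TPM of at least 5 a correlation of 0.287, and only the libraries compared 12 genes at 48 h, where fewer samples estimate the spread. With an estimated correlation 2, 1 and 0 lists passed at 16 h, at 48 h and over time in DMSO, and with fry 1, 2 and 12; the cause was not tested. Other settings gave 16 to 26 genes at 48 h. The sign of Hsd17b10 at 16 h turned without DMSO 16 h replicate 2 (-0.00888; up to 0.12 over the libraries left out) and that of Srd5a1 without erinacine S 16 h replicate 1 (-0.0617; up to 0.39); neither passed with all libraries, and the cause was not tested. Of the other values of named genes under the alternatives, 913 over time, 622 at 48 h, 340 at 16 h and 75 for the difference kept direction and side of the threshold, 55 over time and 69 at 48 h lost the call, and 4 and 11 gained it.

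The replicate block gave 13 genes at 48 h (2 higher and 11 lower), where the numbers do not pair the libraries (correlations -0.02, 0.11 and -0.19, none highest for its own number), and the block within each time gave 17 genes at 48 h and 1 for the difference between times. Under the block within each time no list passed at 48 h with an estimated correlation (adjusted p = 0.115 for the immediate early genes), and 1 passed with fry (0.00675). Over time in DMSO the planned replicate block left the immediate early genes at adjusted p = 0.0501 by the preset test.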

Other observations

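Without erinacine S 48 h replicate 1, a fit whose emphasis was chosen after the data were seen, 107 genes were lower and 7 higher with erinacine S at 48 h, and 97 of these 114 had an unadjusted p under 0.05 with all libraries. Slower activity-regulated genes were among them. The secretogranin gene Scg2, a precursor of neuropeptides, was at 31.8 to 58.9 TPM in the erinacine S libraries of 48 h and at 91.1 to 104 TPM in DMSO (log2 fold change -1.24 ± 0.31, SE, limma adjusted p = 0.201 with all libraries; -1.52 ± 0.30, adjusted p = 0.0494 without replicate 1). The neuropeptide gene Adcyap1 was at 1.48 to 3.30 TPM against 5.03 to 7.01 TPM (-1.38 ± 0.18, SE, adjusted p = 0.00585 without replicate 1). Bdnf and Igf1 also passed without that library, at -1.22 and -0.97 (adjusted p = 0.0199 and 0.0178).

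Klf9, Per1 and Hr were lower too in each erinacine S library of 48 h than in any DMSO library of that time; these 3 genes were picked after their values were seen, and none passed with all libraries. Klf9, which glucocorticoid and thyroid hormone induce, was at 5.94 to 19.6 TPM against 31.7 to 45.9 TPM in DMSO (log2 fold change -1.59 ± 0.33, SE, limma adjusted p = 0.132 with all libraries; -1.12 ± 0.21, adjusted p = 0.043 without replicate 1). The clock gene Per1 was at 22.0 to 32.0 TPM against 35.3 to 39.9 TPM (-0.57 ± 0.13, adjusted p = 0.149; -0.73 ± 0.09, adjusted p = 0.00585 without replicate 1). Hr, a corepressor induced by thyroid hormone, was at 5.01 to 12.3 TPM against 13.7 to 17.9 TPM (-0.88 ± 0.23, adjusted p = 0.216; -0.57 ± 0.15, adjusted p = 0.16 without replicate 1). No list was built around these genes, so they stand for no group.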
